A study of Mus musculus with 7 samples.

How the data were processed

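Polyadenylated RNA from 7 mouse esophageal epithelial cell lines was made into libraries with a strand-specific kit, per the labels' protocols. The deposited values are raw counts per gene in one table of 24047 gene names. Per the submitters' processing notes, STAR 2.5.1b and the mouse build mm9 were used. The counting step, its strand setting and the gene annotation are not given in the sources used here, so genes that overlap on opposite strands, and close paralogs such as the Sprr2 genes, carry that uncertainty. The table lists 92 spike-in names with a total of 0 counts, which were left out, and 27 names in the form of dates, which were kept in the fit and not named. No coordinates are given. Groups and numbers were taken from the sample titles. The labels describe separate cell lines and do not say whether they came from separate animals, so the p-values measure the spread between these lines. Counts of replicate libraries differed far beyond sampling noise (chi-square per degree of freedom 55.9 to 233.6), so no library was a copy of another.

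Differential expression was tested in R 4.3.3 with edgeR 4.0.16, using the quasi-likelihood F test with its default settings, TMM factors, the default expression filter by group and Benjamini-Hochberg adjustment with a threshold of 0.05. The default of this version is the older (legacy) form of the quasi-likelihood fit. The newer form was added as an alternative after the data were seen. That alternative had at first been set to the legacy form by mistake, which only repeated the primary result, and it was corrected when identical counts were noticed. The primary result was left as planned. All 7 libraries entered one fit, so the 3 groups shared one estimate of spread (common biological coefficient of variation 0.485). Adjusted p-values for genes are from this test. Standard errors were derived from the fold change and the F statistic. A group with 0 counts was set to a floor of 3 counts over the group, and ratios with 1 to 3 counts were given with an exact 95% interval. Both cover counting error only.

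A total of 26 gene lists, fixed before the data were examined, were tested with camera in limma 3.58.1 on voom weights, with the preset correlation of 0.01 and again with an estimated correlation. No list was called with an estimated correlation in any comparison. That form of camera rests on the few residual degrees of freedom that 7 libraries in 3 groups leave, so it had little power. Its smallest p in any comparison was 0.0175, for p53 targets in null against WT, with adjusted p = 0.373. A missing call in this form therefore does not show that a list was unchanged. Counts of single genes were also adjusted over each list alone. Such counts were also high in lists that were not called. In mutant against WT, the uncalled list of YAP/TEAD targets had 4 genes higher and 8 lower of 25. In mutant against WT 9 lists were called and 17 were not, in null against WT 10 and 16, and in mutant against null 11 and 15. Genes named in the text followed a rule fixed beforehand. It took the 8 highest and 8 lowest called genes with non-overlapping libraries and at least 5 CPM in the higher group, up to 4 called genes per list or else the 2 with the smallest p, and 12 genes chosen from background knowledge. Predicted models and clones were left out. Collagen genes and Y-linked genes in single libraries were chosen after their values were seen.

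The fit was tested on simulated counts for the 13768 genes with 200 changed genes. The changed genes were drawn only from those with a mean above 5 CPM, so the shares called describe such genes. For mutant against null, mutant against WT and null against WT it called 10, 14 and 4% of genes changed 2-fold, 58, 62 and 60% of those changed 4-fold, and 90, 88 and 90% of those changed 16-fold, with 9, 8 and 9 false calls. The simulation had no differences shared by many genes between lines of a group, so these shares need not hold for the real libraries. There, Trp53 in mutant against null was not called at a log2 fold change of 5.06. A lack of calls therefore does not show a lack of large differences. With the preset correlation, a simulated list of 30 genes raised 2-fold for mutant against WT was called and 0 of 20 unshifted lists were. The estimated correlation was not tried on simulated lists. The simulated genes were drawn independently of each other, so this check says nothing on false calls in lists of correlated genes. In the real data the estimated correlation was 0.907 for mitosis genes in mutant against WT. Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter, a filter of 5 CPM in 2 libraries, a robust fit, fits of only the groups compared, libraries thinned to 12751118 counts, a replicate block and leaving out each library. The fry set test, the replicate block for null against WT and a separate WT library for each of the 2 comparisons with WT were added after the data were seen. The last was first run on all 14375 genes of those fits (correlations 0.67 and 0.726) and then limited to the 13758 of them that were in the primary fit. The fibroblast test was first run on the 4 libraries together and was divided into mutant 2 and the other 3 after its values were seen. Gene order for the neighbour test came from the GRCm38.p6 RefSeq gene table, used only for which genes neighbour each other, and 94.8% of 10436 expressed genes matched by name.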

Results

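RNA was sequenced from 7 mouse esophageal epithelial cell lines grown in plastic dishes in keratinocyte serum-free medium. There were 2 wild-type (WT) lines, 3 lines with the missense allele p53R172H (mutant) and 2 lines without p53 (null, numbered 1 and 3). Every mutant and null line also carried the label 4NQO, the short name of the esophageal carcinogen 4-nitroquinoline 1-oxide, and neither WT line did. Total counts were 31283848 and 12751118 in WT 1 and WT 2. They were 47000225, 41325469 and 42754434 in mutant 1, 2 and 3, and 33598210 and 25469853 in null 1 and null 3. The 13768 genes that passed the filter held at least 99.95% of each library's counts. Expression values are TMM-normalized CPM, given as mean ± SD.

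The targeted gene was read first. Trp53, which encodes p53, stood at 202 ± 13.4 CPM in WT (n = 2), 225 ± 46.3 CPM in mutant (n = 3) and 6.72 ± 2.85 CPM in null lines (n = 2). The single null libraries had 8.73 and 4.71 CPM, and the lowest of the other 5 libraries had 171.6 CPM. Null lines were lower than WT by a log2 fold change of -4.91 (SE 0.379, edgeR adjusted p = 0.0149), whereas mutant and WT differed by 0.15 (SE 0.292, adjusted p = 0.742). Xist, the noncoding RNA of the inactive X chromosome, was at 675.4 CPM in WT 1 and 1653 CPM in WT 2 and at most 0.964 CPM in every other library. Ddx3y, on the Y chromosome, was at 67.4 to 77.0 CPM in the mutant libraries and 96.4 CPM in null 3. It was at 0.987 CPM in WT 1, 0.0812 CPM in WT 2 and 0.0304 CPM in null 1.

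**Figure D1:**
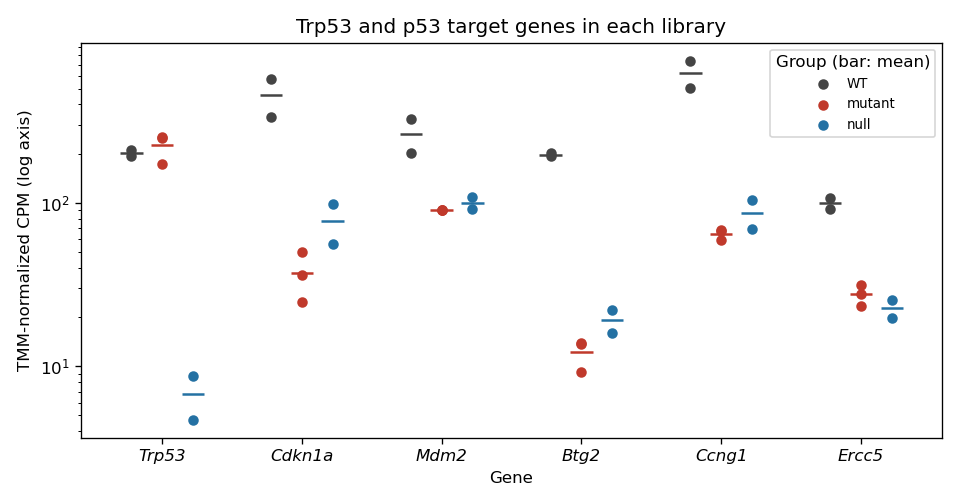
Normalized CPM (log axis) of Trp53 and 5 genes known as p53 targets, one point per library and a bar at each group mean. Trp53 is at 8.73 and 4.71 CPM in the null libraries and at 171.6 CPM or more in the other 5, and Btg2 averages 197 CPM in WT, 12.2 in mutant and 19.1 in null.

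The comparison of mutant with WT lines asks how esophageal cells carrying p53R172H and the 4NQO label differ from WT cells. Genes that p53 is known to activate fell. Cdkn1a, the cell cycle inhibitor p21, was at 37.0 ± 12.7 CPM in mutant (n = 3) against 455 ± 168 CPM in WT (n = 2), a log2 fold change of -3.62 (SE 0.408, adjusted p = 0.0199). Btg2 changed by -4.01 (SE 0.249, adjusted p = 0.00788), Ccng1 by -3.26 (SE 0.247, adjusted p = 0.0081), and Mdm2, the ubiquitin ligase of p53, by -1.55 (SE 0.216, adjusted p = 0.0218). Of 46 p53 target genes tested, 17 fell and none rose, and 23 were lower when adjusted over the list alone. The list was called lower by camera (adjusted p = 2.66e-10), with adjusted p = 0.504 with an estimated correlation.

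Genes of epithelial junctions and squamous differentiation also fell in mutant lines. Of 40 genes for junctions and epithelial transcription factors, 19 fell and none rose (31 lower when adjusted over the list alone), among them the transcription factor Grhl1 (-2.50, SE 0.347) and the membrane protease St14 (-2.57, SE 0.372). Cdh1, E-cadherin, was at 403 ± 99.9 CPM against 811 ± 170 CPM and did not pass (adjusted p = 0.0599). Of 51 genes of suprabasal differentiation, 13 fell and none rose (17 lower when adjusted over the list alone). Sprr2d, a cornified envelope precursor, was at 0.155 ± 0.155 CPM in mutant and 105 ± 8.44 CPM in WT, and the cornified envelope protein Ppl changed by -2.81 (SE 0.304, adjusted p = 0.0192). Both lists were called lower (adjusted p = 2.55e-16 and 1.51e-12), each with adjusted p = 0.504 with an estimated correlation. Among 26 basal epithelial genes 2 fell and 1 rose (5 lower and 1 higher when adjusted over the list alone). Krt5, the basal keratin, fell from 17610 ± 5353 to 3041 ± 1043 CPM (adjusted p = 0.0289) and the laminin chain Lama3 fell by 2.08 on the log2 scale, while Dlk2 rose by 2.07. Of 4 stress keratins, Krt16 fell by 2.95 (SE 0.455, adjusted p = 0.0253), and all 4 were lower when adjusted over the list alone. The basal and stress keratin lists were called lower (adjusted p = 0.0241 and 0.00385), each with adjusted p = 0.539 with an estimated correlation, and the basal list had adjusted p = 0.125 without WT 2.

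Genes linked to mesenchymal transition moved the other way. Of 35 tested, 4 rose and 1 fell (14 and 2 when adjusted over the list alone). Zeb1, a repressor of E-cadherin, had 3 counts over both WT libraries and 6017 over the mutant libraries, a ratio of 620 (95% counting interval 212 to 3010). Its relative Zeb2 was at 72.2 ± 9.75 CPM against 3.99 ± 0.550 CPM (adjusted p = 0.0355) and Sparc, a matrix protein, at 853 ± 357 against 29.9 ± 13.1 CPM (adjusted p = 0.0306), while Msn fell by 1.01. Vim, the intermediate filament vimentin, was at 582 ± 241 CPM against 2.03 ± 1.95 CPM with adjusted p = 0.0599. The list was called higher (adjusted p = 0.00426; adjusted p = 0.781 with an estimated correlation). Fibroblast markers were not called as a list (adjusted p = 0.277). They stood at a mean log2 ratio to WT of 3.65, 0.235 and 2.54 in mutant 1, 2 and 3.

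Cytokine genes and NF-kB targets included 6 that fell and none that rose among 33 (10 lower and 1 higher when adjusted over the list alone). The list was mixed, with 15 of the 33 at a log2 fold change above 0 and a median of -0.544. Csf3, which encodes the granulocyte growth factor G-CSF, was at 4.05 ± 1.90 CPM in mutant and 188 ± 65.1 CPM in WT (adjusted p = 0.0113). Lif changed by -1.94 (SE 0.192), Tnf by -6.27 (adjusted p = 0.0264) and Nfkbia, an inhibitor of NF-kB, by -1.53 (SE 0.267). The list was called lower (adjusted p = 0.00426; adjusted p = 0.746 with an estimated correlation). The mean log2 ratio of the list to WT was -0.025 in mutant 1, -1.45 in mutant 2 and -0.948 in mutant 3, against -0.0214 and 0.0214 in WT 1 and WT 2. The replication genes Slbp and Ccne2 rose by 1.27 and 1.75, the only 2 of 32 in their list with or without adjustment over the list alone. That list was called higher (adjusted p = 0.0392; adjusted p = 0.93 with an estimated correlation), but not without WT 1 or mutant 1 (adjusted p = 0.899 and 0.297) or with a replicate block (adjusted p = 0.0981). Nsdhl fell by 1.63 as the only called gene of 24 for cholesterol synthesis, also when adjusted over the list alone, and that list was called lower (adjusted p = 0.00734; adjusted p = 0.93 with an estimated correlation), but not without WT 1 (adjusted p = 0.168).

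Single genes changed in lists that were not called, though Rab25 also belongs to the junction list, which was called lower. In endocytic recycling, the log2 fold changes of Rab25, Myo5b and Rab8b were -2.54, -2.14 and 1.25 (adjusted p = 0.0249, 0.0352 and 0.0429), while Rab11fip1 was at 31.1 ± 8.0 against 60.0 ± 10.3 CPM (adjusted p = 0.1). In the Notch pathway, Notch1, Hes1 and Nrarp changed by -3.42, -1.66 and -2.33 (adjusted p = 0.0497, 0.0383 and 0.0376). The glutathione transferase Gstm1 rose by 3.46, and the pentose phosphate enzymes G6pdx and Tkt changed by -1.63 and -1.38. Among the largest changes, C1qtnf3 and St6galnac4 had no count in WT and were at least 206-fold and 196-fold higher in mutant lines, and Slit3 had 2 counts in WT, a ratio of 1140 (95% counting interval 316 to 9440). Pbp2 had no count in mutant lines and was at least 589.7-fold lower. The transcription factor Zfp750, a member of the suprabasal list, fell by 7.94 on the log2 scale.

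In all, 1022 genes were called in mutant against WT, 454 higher and 568 lower, and 4199 had an unadjusted p under 0.05. DESeq2 called 3197, with the balance turned (1714 higher, 1483 lower). Leaving out WT 1 or WT 2 left 0 calls by edgeR, with 2840 and 2207 genes at an unadjusted p under 0.05, and leaving out mutant 2 or mutant 3 left 37 and 6. Genotype, the 4NQO label and the sex-linked genes above all separated these groups.

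The comparison of null with WT lines asks the same of cells without p53. Here too, genotype, the carcinogen label and Xist all separated the groups. Besides Trp53, the p53 targets Btg2, Ccng1 and the repair endonuclease Ercc5 fell, by log2 fold changes of -3.37 (SE 0.285), -2.85 (SE 0.284) and -2.13 (SE 0.235), with adjusted p = 0.0191, 0.0295 and 0.0397. Cdkn1a was at 77.6 ± 30.2 CPM in null (n = 2) against 455 ± 168 CPM in WT (n = 2), with adjusted p = 0.0871, and Mdm2 at 99.9 ± 12.5 against 265 ± 88.0 CPM, with adjusted p = 0.0827. Of 46 p53 targets, 3 fell and none rose, and 21 were lower when adjusted over the list alone. The list was called lower (adjusted p = 1.49e-11; adjusted p = 0.373 with an estimated correlation).

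Genes that rose in null lines included Enpp4 (6.20, SE 0.400, adjusted p = 0.0149), Trim47 (5.82, SE 0.443, adjusted p = 0.0149), Hspb8, a small heat shock protein (2.78, SE 0.294, adjusted p = 0.0397), and Nnt, the mitochondrial transhydrogenase, at 59.2 ± 3.54 CPM against 15.9 ± 0.394 CPM. St6galnac4 had no count in WT and was at least 135-fold higher. Slitrk6 and Fbxw9 changed by -5.17 and -2.37, and Xist was among the called genes.

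Interferon-stimulated genes had a median log2 fold change of 2.30 in null against WT, with 33 of 36 above 0. None was called over all genes and 5 were higher when adjusted over the list alone. The mean log2 ratio of the interferon list to WT was 2.02 in null 1 and 1.23 in null 3, against 0.482 in WT 1 and -0.482 in WT 2. Xaf1 was at 48.7 ± 12.3 CPM in null and 4.55 ± 4.25 CPM in WT (adjusted p = 0.124). Antigen presentation genes had a median of 1.47, with none called over all genes and 6 of 16 higher when adjusted over the list alone. Their mean log2 ratio to WT was 2.13 in null 1 but 0.892 in null 3, against 0.212 in WT 1 and -0.212 in WT 2. B2m, the light chain of MHC class I, was at 1370 ± 1002 against 145 ± 18.8 CPM (adjusted p = 0.1). Both lists were called higher (adjusted p = 5.31e-08 and 0.000309), each with adjusted p = 0.69 with an estimated correlation. Mitosis genes were called lower (median -1.50, adjusted p = 6.13e-11; adjusted p = 0.69 with an estimated correlation), with none of 32 called singly over all genes or when adjusted over the list alone. Their mean log2 ratio to WT was -2.65 in null 1 and -0.549 in null 3, against -0.482 in WT 1 and 0.482 in WT 2, so the size of the fall rested mostly on null 1. Without null 1 the list had adjusted p = 0.00906. Replication, basal, suprabasal, stress keratin and junction lists were also called lower (adjusted p = 0.000173, 9.58e-05, 2.07e-05, 0.00658 and 0.00682), and the glycolysis and hypoxia list higher (adjusted p = 0.00491). With an estimated correlation these had adjusted p = 0.808, 0.373, 0.68, 0.642, 0.798 and 0.69. None of their genes was called over all genes. When adjusted over the list alone, 1 replication gene, 6 basal genes, 4 suprabasal genes and 1 stress keratin were lower, 1 basal gene was higher, no junction gene passed, and 1 glycolysis gene was higher and 1 lower. The fibroblast and muscle marker lists were not called by camera (adjusted p = 0.424 and 0.961), but the null lines differed in them. The mean log2 ratio to WT was 3.57 in null 3 and -0.0759 in null 1 for fibroblast markers, and 1.53 and -0.699 for muscle markers. The replication call was lost without null 1 (adjusted p = 0.147), the junction call without WT 1 or null 3 (adjusted p = 0.266 and 0.447) and the glycolysis call without WT 2 or null 1 (adjusted p = 0.0745 and 0.316).

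In all, 19 genes were called in null against WT, 10 higher and 9 lower, and 2777 had an unadjusted p under 0.05. DESeq2 called 1548 and limma-voom 0, with 2155 genes at an unadjusted p under 0.05 in limma-voom. Without WT 1, WT 2 or null 3 no gene was called by edgeR (2147, 1126 and 2189 at an unadjusted p under 0.05), and without null 1 there were 55, 47 higher and 8 lower.

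**Figure D2:**
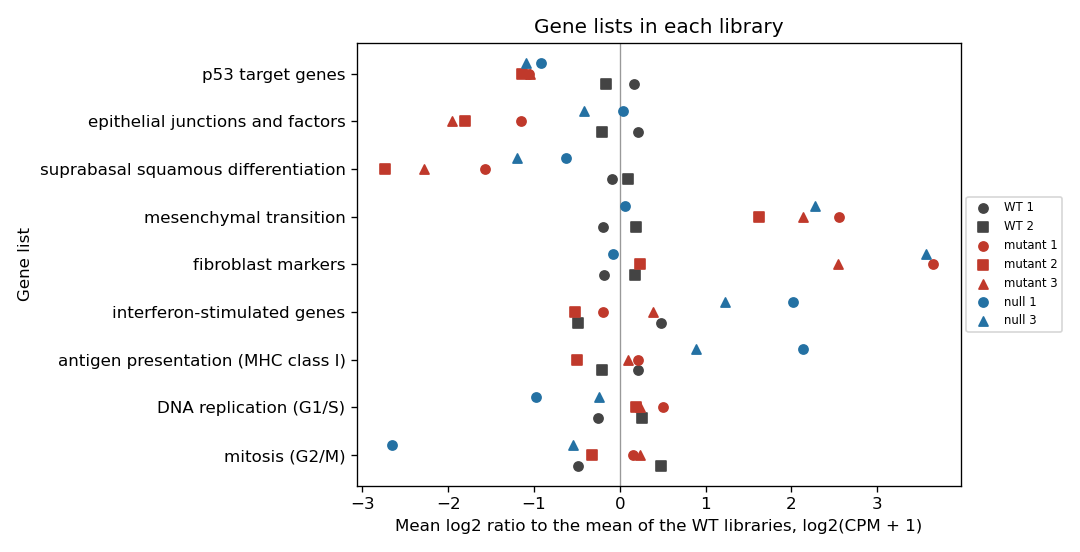
Mean log2 ratio of each gene list to the mean of the WT libraries, on the log2(CPM + 1) scale (horizontal axis), for 9 gene lists (vertical axis), with one symbol per library. The p53 target list lies between -1.14 and -0.916 in all 5 mutant and null libraries, and the mesenchymal list at 0.0569 in null 1 and 2.27 in null 3.

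The comparison of mutant with null lines, which share the 4NQO label, asks whether a missense p53 differs from its loss. The log2 fold change of Trp53 was 5.06 (SE 0.373), with an adjusted p of 0.0555, the smallest of any of the 13768 genes. Several alternative settings, given below, did call Trp53. Cdkn1a was at 37.0 ± 12.7 CPM in mutant (n = 3) and 77.6 ± 30.2 CPM in null (n = 2), with adjusted p = 0.317. The p53 target list had a median log2 fold change of -0.11 and was not called (adjusted p = 0.526), with no gene called over all genes and 1 lower when adjusted over the list alone.

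Interferon-stimulated genes were called lower in mutant than in null lines (median -2.18, adjusted p = 3.31e-18; adjusted p = 0.543 with an estimated correlation). None was called over all genes and 14 of 36 were lower when adjusted over the list alone. Ifih1, a sensor of viral RNA, was at 1.59 ± 0.689 CPM in mutant and 15.4 ± 3.67 CPM in null. The antigen presentation list was called lower too (median -1.58, adjusted p = 1.63e-07; adjusted p = 0.566 with an estimated correlation), with 9 of 16 lower when adjusted over the list alone. H2-K1, a class I heavy chain, was at 154 ± 46.2 against 883 ± 575 CPM. The mean log2 ratio of the antigen presentation list to WT was 2.13 in null 1 and 0.892 in null 3.

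Junction genes were called lower in mutant than in null (median -1.24, adjusted p = 8.23e-17; adjusted p = 0.543 with an estimated correlation), 23 of 40 when adjusted over the list alone. Suprabasal genes were called lower as well (median -1.79, adjusted p = 8.93e-09; adjusted p = 0.543 with an estimated correlation), 3 of 51 when adjusted over the list alone. Replication genes were called higher (median 0.95, adjusted p = 1.26e-14; adjusted p = 0.543 with an estimated correlation), 13 of 32 when adjusted over the list alone, and mitosis genes higher (median 1.38, adjusted p = 4.54e-15; adjusted p = 0.566 with an estimated correlation), none when adjusted over the list alone. The mean log2 ratio of the mitosis list to WT was 0.158, -0.321 and 0.236 in mutant 1, 2 and 3, -2.65 in null 1 and -0.549 in null 3, and without null 1 the list had adjusted p = 4.46e-07. The mesenchymal list was called higher (median 0.48, adjusted p = 0.0058; adjusted p = 0.621 with an estimated correlation), none when adjusted over the list alone, and had adjusted p = 0.85 without null 1 and 0.118 without mutant 1. Cytokine genes were called lower (adjusted p = 1.88e-05; adjusted p = 0.543 with an estimated correlation), 5 of 33 when adjusted over the list alone. Glycolysis and cholesterol synthesis lists were called lower and the sex-linked list higher (adjusted p = 0.0104, 0.0132 and 0.0132; adjusted p = 0.621, 0.814 and 0.566 with an estimated correlation), and each lost its call without null 1 (adjusted p = 0.524, 0.485 and 0.213), where cholesterol synthesis turned to higher and sex-linked genes to lower. The sex-linked call was also lost with a replicate block (adjusted p = 0.431). None of their genes passed when adjusted over the list alone. Calls were also lost without mutant 1 for glycolysis and sex-linked genes (adjusted p = 0.0502 and 0.0558) and without mutant 2 for cholesterol synthesis (adjusted p = 0.0964).

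No gene was called in mutant against null by edgeR, with 1924 genes (14.0%) at an unadjusted p under 0.05. Null 1 and null 3 correlated at 0.895 across genes, so the null mean joins unlike lines. DESeq2 called 604 and limma-voom 0, and without null 3 edgeR called 22.

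The mutant and null comparisons share the WT libraries. Of the 19 genes called in null against WT, 18 were called in mutant against WT in the same direction, 10 higher and 8 lower, and the exception was Trp53. Independent lists of these sizes would share 0.33 higher and 0.371 lower, a figure that leaves the common controls out of account. In 20 simulations of unchanged groups against the same controls the 2 comparisons gave means of 0.05 and 0.1 calls, too few to show how many shared calls the controls alone would give. Across genes, which are not independent replicates, the fold changes correlated at 0.852 against a simulated mean of 0.576. Their covariance was 2.985 against 0.459, a difference of 2.525. With mutant lines set against one WT library and null lines against the other, which was added after the data were seen, the fold changes correlated at 0.705 and 0.765 with covariances of 3.036 and 3.169 in the 2 arrangements, against simulated means of 0.0458 for the correlation and 0.0754 for the covariance. With 1 WT library per comparison no gene was called, whether the 2 comparisons shared it or not, so the shared calls could not be tested this way. Whether part of the 18 comes from the common controls was left open. All mutant and null lines also carried the carcinogen label and had almost no Xist, unlike both WT lines. Xist was itself among the 18. The overlap therefore cannot be assigned to the change in p53. Without WT 1, WT 2 or null 3 no shared call remained, and without mutant 2, mutant 3 or null 1 there were 7, 3 and 53.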

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

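The replication gene list was called in opposite directions against WT, higher in mutant and lower in null lines, and the test of the difference itself, mutant against null, gave adjusted p = 1.26e-14 (adjusted p = 0.543 with an estimated correlation). The 2 calls against WT had adjusted p = 0.93 and 0.808 with an estimated correlation. The mean log2 ratio of the list to WT was 0.499, 0.19 and 0.238 in mutant 1, 2 and 3 and -0.981 and -0.246 in null 1 and null 3. WT 1 and WT 2 themselves stood at -0.254 and 0.254. The call against WT was lost without WT 1 or mutant 1 for mutant lines (adjusted p = 0.899 and 0.297) or with a replicate block (adjusted p = 0.0981), and without null 1 for null lines (adjusted p = 0.147).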

How the results depend on the processing

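The newer quasi-likelihood form, fry, the replicate block for null against WT and separate WT libraries for the 2 comparisons were chosen after seeing the data; the other settings were planned. RLE, upper-quartile factors, the stricter filter and thinning gave 1 call each in mutant against null, no filter 2, the newer form 1, and DESeq2 604. Trp53 was the 1 gene called with RLE factors (adjusted p = 0.0487), upper-quartile factors (0.0472), the stricter filter (0.0391), thinning (0.0127) and the newer form (0.0321). It also passed with no filter (0.00697) and DESeq2 (3.56e-55). It did not pass in the primary fit (0.0555), the robust fit (0.0542), limma-voom (0.0763), with a replicate block (0.296) or with only the groups compared (0.432). In null against WT no filter gave 77, the newer form 55, DESeq2 1548 and limma-voom 0. In mutant against WT DESeq2 gave 3197 (1714 higher, 1483 lower), limma-voom 743 (200 higher, 543 lower) and the newer form 1335. The newer form split null against WT as 20 higher and 35 lower. Leaving out one library gave 0 to 22 calls in mutant against null, 0 to 1420 in mutant against WT and 0 to 55 in null against WT; a lone library was assumed to vary like the others, and the cause beyond fewer samples was not tested. Shared calls were 1137 with DESeq2, 74 with no filter and 0 to 53 leaving out one library, and 0 in both arrangements of separate WT libraries. Trp53 in null against WT ranged from -5.43 to -4.53. Lists called fell to 0 in each comparison with an estimated correlation. With fry they fell to 0 in mutant against null, 3 in mutant against WT and 1 in null against WT. The 3 were p53 targets, suprabasal genes and junction genes (fry adjusted p = 0.016, 0.0474 and 0.0474). The 1 in null against WT was p53 targets (fry adjusted p = 0.0495). Without null 1, 2 lists turned in mutant against null: cholesterol synthesis (adjusted p = 0.485; 2.44e-06 without null 3) and sex-linked genes (adjusted p = 0.213; 0.000286 without null 3); the cause was not tested. Of 113 gene results examined, none changed direction under any setting. All 69 that were called lost the call when some library was left out, and the other 44 were not called. Nothing in the labels says that the replicate numbers in the titles pair the lines. Same-numbered libraries deviated from their group means with correlations of -0.405 to 0.138. In a group of 2 libraries the deviations mirror each other, so these values cannot decide whether lines were paired. With a replicate block 0 genes were called in mutant against null and 0 in mutant against WT (2887 at an unadjusted p under 0.05), and 0 in null against WT (1454 at an unadjusted p under 0.05), where 12 lists were called; the block leaves 2 residual degrees of freedom. Thinning to the shallowest total left 1055 calls in mutant against WT.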

Other observations

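The mutant and null lines were not uniform. Vim was at 343, 577 and 825 CPM in mutant 1, 2 and 3 and 225 CPM in null 3, but at 2.71 CPM in null 1. Col3a1, a fibrillar collagen, was at 148 and 183 CPM in mutant 1 and 3 and 276 CPM in null 3, and at 0.214 CPM in mutant 2 and 0.0913 CPM in null 1. Cdkn2a, the locus of p16 and Arf, averaged 215 ± 62.5 CPM in mutant, 202 ± 119 CPM in null and 52.5 ± 17.8 CPM in WT lines, with adjusted p = 0.0525 for mutant and 0.134 for null. B2m was at 2078 CPM in null 1 and 662 CPM in null 3.

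Among the tests below, those of library depth and of neighbouring genes were written before their result was seen and the others after it.

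No gene was called by edgeR in mutant against null (1924 at an unadjusted p under 0.05; DESeq2 604, limma-voom 0), and null 1 correlated better with WT 1 (0.94) than with null 3 (0.895). Admixed WT cells are argued against, because Xist in null 1 allows a share of at most 0.000829. A null label on a line with p53 is argued against too, because the higher null library had 0.0509 of the lowest other Trp53 level. The 2 null lines differed from each other. Their correlation of 0.895 lay below the lowest among mutant libraries (0.919). Null 3 correlated with mutant 1, 2 and 3 at 0.9584, 0.8971 and 0.923, and null 1 with them at 0.8785, 0.9003 and 0.8891. Mutant against null is thus a contrast with the mean of 2 unlike lines. Whether these hold different states or vary as lines do stays open, because each is 1 line.

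Vim was high in the mutant lines and null 3, and Col1a1 and Col3a1 were high in mutant 1, mutant 3 and null 3 but not in mutant 2. Col1a2 was at 326.4 CPM in mutant 1, 0 in mutant 2, 1.514 in mutant 3 and 10.06 in null 3, against at most 1.056 CPM in WT. Fibroblasts growing in the cultures stay open. Summed Col1a1, Col1a2, Col3a1 and Dcn over Vim differed 4.07-fold between mutant 1, mutant 3 and null 3, inside the limit of 5, but 2 of the 4 genes taken singly passed that limit, Col3a1 at 5.55-fold and Col1a2 at 518-fold. In mutant 2 the summed ratio was 0.00765 against 0.374 to 1.52 in the other 3, which excludes fibroblasts only if their profile is fixed, and that was assumed and not measured. A change of the epithelial cells themselves stays open as well. The median log2 ratio to WT of the junction list was at most -0.557 in these 4 libraries. Fibroblasts taking up part of a culture would lower junction genes too, so this value does not separate the explanations. Across libraries the junction fall did not follow fibroblast markers. Mean log2 ratios to WT of the junction list were -1.15, -1.8 and -1.96 in mutant 1, 2 and 3 and -0.413 in null 3. Fibroblast markers stood at 3.65, 0.235, 2.54 and 3.57. If the fibroblast profile is fixed, this argues against fibroblasts as the only source of the junction fall. The source of the mesenchymal genes stays open. Bulk libraries cannot place a transcript in a cell, so a change of the epithelial cells stays a hypothesis.

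The genes called in mutant against WT were not explained by depth, since 1055 were called with every library thinned to the same total. The sex of the lines cannot be told apart from genotype, since the higher WT library had 0.0146 of the lowest mutant Ddx3y level. Copy number changes of chromosome segments stay open. Genes 10 to 20 places apart on an autosome correlated at 0.0331 to 0.0678 in the 5 lines, above all 100 shuffled orders. The limit set beforehand, over 0.05 in each line, was missed in mutant 2, mutant 3 and null 3 (0.0391, 0.0393 and 0.0331), and the bound set against it, under 0.05 in the lines, was passed by mutant 1 and null 1. WT 1 over WT 2 gave 0.0684, so the measure did not set these lines apart from WT. Chromosome 3, singled out after its values were seen, had median log2 ratios to WT of 0.436, 0.477 and 0.533 in the mutant libraries and 0.24 and 0.261 in the null libraries, against 0.154 for WT 1 over WT 2.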
